A study of Brassica napus with 3 samples.

How the data were processed

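The study measured where BnaC3.LFY binds genomic DNA of rapeseed (Brassica napus) by DNA affinity purification sequencing (DAP-seq). In this assay a transcription factor made outside the plant is incubated with a library of fragmented, naked genomic DNA, and the DNA it retains is sequenced. Per the labels' protocols, genomic DNA was extracted with the CTAB method and made into libraries with a commercial DNA kit. The labels call the tissue both shoot apices and inflorescence. The title of the series names ChIP-Seq, while its design text and the sample titles name DAP, which was followed here. The 3 samples are 2 DAP replicates of BnaC3.LFY and 1 input library. Nothing in the labels says whether the replicates came from separate plants, DNA preparations or protein preparations.

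Per the submitters' processing notes, fastp, Bowtie2, SAMtools, MACS2 and HOMER were used. Versions and parameters are not given in the sources used here. The sequence names of the deposited list carry the name of the Westar v0 assembly, so all positions are in that build and are printed counted from 1. The deposited table is a single peak list for the whole series with 7 columns and no header. It gives an interval, a score, a fold enrichment, a -log10 p and a -log10 q per peak, and it names no sample, summit or gene. The deposited score follows 10 times the deposited -log10 q, which lay between 0 and 1 above it in every row. The deposited scores are not all whole numbers, and 304 have a fraction that a mean of 2 whole numbers cannot have. The deposited fold was read as a ratio of the pileup of DAP reads to the local background of the peak caller, from the order of the columns. A pseudocount of 1 in both was assumed for the recovery described next, which succeeded for part of the rows only. Each of these is the peak's own value as the authors gave it. Read totals per library are not in this list, so the sequencing depth is unknown.

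How the authors combined the replicates is not given in the sources used here, and it was examined from the values. A single line of the peak caller holds a whole-number score and values with at most 6 significant digits. A row was said to carry the averaging sign where its score was fractional or where its fold, -log10 p or -log10 q had more digits than that. Tested on simulated data with 10000 rows, the sign appeared in 94.1% of means of 2 peak lines and in 0% of single lines. For rows without the sign, the whole-number pileup and the local background that together give the deposited fold and the deposited -log10 p under a Poisson model were sought, and accepted where -log10 p was met within 0.001. This worked for 12950 of 20920 rows (61.9%), against 0.727% when -log10 p was moved at random by up to 0.2, and in 954 simulated peaks it returned the true pileup in 100% of cases. The accepted rows had a median pileup of 14 reads (10th to 90th percentile 10 to 20) over a median background of 2.31 reads, which is the counting depth behind a weak peak. Rows without the sign were also assigned, within 0.015, to 1 of 2 curves of -log10 q against -log10 p, read from the narrowest rows and from the rows of the most frequent width. Recovery worked for 98.0% of rows on the second curve and 2.56% on the first, so recovered backgrounds describe almost only 1 of the families of rows.

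Several comparisons fixed before the data were examined needed the Westar v0 genome sequence or annotation, which was not used here: positions relative to genes, the LEAFY core motif at summits, motif share against peak strength, fixed lists of flowering, hormone, defence and housekeeping genes, the LEAFY loci and the A and C copies of genes. The gene table at hand describes the Da-Ae assembly, and no coordinates were carried between builds. The rule for named peaks, also fixed before the data were examined, then reduces to the 10 peaks of highest fold enrichment on nuclear chromosomes, given by position.

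Chromosome span was taken as the end of the last peak, since chromosome lengths were not at hand. The plan made before the data were examined held peak counts only where lengths were missing. Density per Mb of this span, the strong peaks, the classes of fold and the regional and spacing tests were chosen after seeing the data. Strong peaks are the 10% of peaks with the highest fold, which is a fold of at least 16.1. The A and C subgenomes were compared over chromosomes (10 A, 9 C) with a two-sided exact permutation test of the difference in means, over all 92378 splits. Benjamini-Hochberg adjustment was applied over the 13 measures compared in this way and separately over 8 classes of fold. These p-values measure the spread between chromosomes, not between libraries. Of 40 simulated comparisons without a shift, 3 passed 0.05, and of 20 with a shift of 3 SD, 20 passed. Peaks were counted in windows of 100 kb, and a window was called dense from 20 peaks, a minimum raised from 15 after both had been seen. Even placement was modelled by 1000 random placements of each chromosome's peaks along its span. Spacing was tested against 1000 placements of the same intervals, without overlap, inside their own 100 kb window. An earlier version let the placements overlap and counted midpoints within 1000 bp, and it gave the opposite direction. It was replaced because no peaks of the list overlap, and each of its choices was then tried alone. The averaging sign was also compared among peaks narrower than 472 bp, which is 2 times the narrowest width and too narrow to join 2 peaks of 1 call side by side. On 62314 randomly placed simulated peaks the spacing test differed from its expectation by -0.067 percentage points. Distances of dense stretches to long peak-free intervals were compared with 1000 draws of random windows holding a peak, and strong with other peaks by an exact test over the signs of the 19 chromosome differences. Binomial intervals are 95% Wilson intervals and cover counting error only. Stricter limits of -log10 q (5 and 10), the peaks with a fold above the median, merging of overlapping intervals, other windows and cuts, and subsets by the averaging sign were tried. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.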

Results

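DAP-seq was used to map where BnaC3.LFY, the copy of LEAFY carried on chromosome C03 of rapeseed, binds the genome. LEAFY is a plant-specific transcription factor that gives young primordia on the flank of the shoot apex the identity of flowers. Rapeseed is an allotetraploid: its A chromosomes descend from a Brassica rapa ancestor and its C chromosomes from a Brassica oleracea ancestor. The data comprised 2 DAP libraries and 1 input library, brought together by the authors in 1 list of binding peaks on the Westar v0 assembly. The list held 62949 peaks on 98 sequences. Of these, 62314 (99.0%) lay on the 19 chromosomes and 635 on 79 unplaced scaffolds. No neighbouring peaks overlapped, and together the peaks on chromosomes covered 2.71% of the 933 Mb chromosome span. As 1 list was analysed, no value below has an error between the replicate libraries. Spread is given between chromosomes.

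The peaks ranged from weak enrichment, with a lowest fold of 1.98, to very strong sites. The median fold enrichment over background was 6.08, with quartiles of 4.68 and 9.41 and the strongest at 81.8. A fold of at least 20 was reached by 3952 peaks and a fold of at least 50 by 163. The median -log10 q was 10.1, and 31873 peaks (50.6%) had a -log10 q of at least 10. Peaks were 366 bp wide at the median, with a range of 236 to 5707 bp, and the median width grew from 287 bp in the lowest decile of fold to 521 bp in the highest.

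The 10 peaks of highest fold lay on A02, A06, C03, C04, C06, C07 and C08, and all 10 carried the sign of averaging over more than 1 line of the peak caller. The strongest, with a fold of 81.8, was on C06 from 15141547 to 15142180. It was followed by a peak on C07 from 36387544 to 36388127 with a fold of 78.5. The third, on C03 from 36525967 to 36526652, had a fold of 77.6. A peak on C04 from 33273411 to 33273985 had a fold of 76.2. The strongest peak of the A subgenome, on A06 from 5158678 to 5159299, had a fold of 74.2. C07 held another pair, from 7201729 to 7202339 with a fold of 74.0 and from 6879550 to 6880157 with a fold of 73.9. C08 held a peak of 74.0-fold from 28732375 to 28733076. The last of the 10 were both on A02, from 26558226 to 26558885 with a fold of 73.6 and from 32032200 to 32032849 with a fold of 72.8. Whether these sites lie in promoters, introns or intergenic DNA was not analysed here, and the same holds for the BnaC3.LFY locus itself. Of the 100 strongest peaks on chromosomes, 68 lay on C chromosomes, which make up 58.8% of the chromosome span.

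Whether a peak's values were averaged over more than 1 line of the peak caller was read from the averaging sign, an inference from the digits of the values. The sign was present in 41915 peaks (66.6%). Corrected for the 94.1% of simulated averages that show it, about 70.8% of the peaks were means over more than 1 line. Such lines may come from different calls or from joined neighbours of 1 call, and the sign cannot tell these apart. The sign was present in 21.7% of the lowest decile of fold (95% Wilson interval 20.7 to 22.7%), in 65.6% of the fifth decile (64.4 to 66.8%) and in 94.6% of the highest (94.0 to 95.1%). In the top 3 deciles, from a fold of 8.38 upwards, the share was 94.0 to 94.6%, against the 94.1% of simulated averages. Rows without the sign fell into 2 families. Of 16985 such rows with a -log10 p between 5 and 15, 5273 (31.0%) lay on 1 curve relating p to q, with a minimum width of 236 bp. Another 10531 (62.0%) lay on a second curve, with a minimum width of 242 bp, and 1181 lay within 0.015 of neither. The first curve was read from rows narrower than 242 bp and the second from rows of 242 bp. These minimum widths therefore largely follow from that choice and are no separate trait of the families. A whole-number pileup could be recovered for 98.0% of the rows on the second curve and for 2.56% of those on the first, where values moved at random gave 0.727%. None of the 1290 peaks narrower than 242 bp carried the sign.

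**Figure D1:**
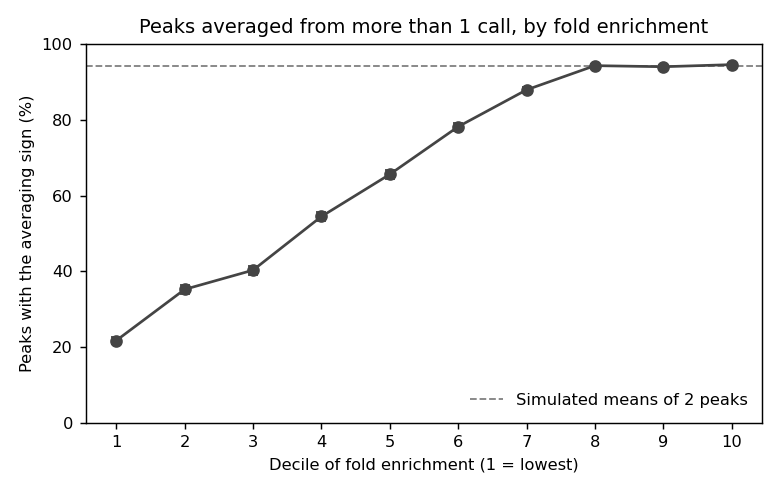
Share of peaks with the averaging sign (percent, vertical axis) in each decile of fold enrichment (horizontal axis, 1 lowest, 10 highest), with 95% Wilson intervals as bars; the dashed line is the 94.1% found in simulated means of 2 peaks. The share climbs from 21.7% in the lowest decile to 94.6% in the highest.

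In the full list, the A and C subgenomes carried peaks at a similar density but differed in strong peaks. A chromosomes held 64.8 ± 7.36 peaks per Mb (SD, n = 10 chromosomes) and C chromosomes 67.0 ± 2.68 (SD, n = 9), a difference below the spread between chromosomes (exact permutation p = 0.407, adjusted p = 0.530). With only peaks at a -log10 q of at least 10, the difference passed, at 3.37 per Mb (exact permutation p = 0.0212). It also passed above the median fold (3.27 per Mb, exact permutation p = 0.0461) and without windows of 15 or more peaks (4.86 per Mb, exact permutation p = 0.0164). It did not pass at a -log10 q of at least 5, without A09, or among peaks with or without the averaging sign. Strong peaks stood at 5.46 ± 0.660 per Mb on A and 7.50 ± 0.352 per Mb on C chromosomes, 37.4% higher on C (exact permutation p = 1.08e-05, the smallest that 92378 splits allow, adjusted p = 4.69e-05). Every C chromosome (6.99 to 8.01 per Mb) lay above every A chromosome (4.56 to 6.38 per Mb). Peaks of lower fold had nearly equal means, 59.3 ± 6.89 per Mb on A and 59.5 ± 2.39 on C (exact permutation p = 0.936). Strong peaks accordingly made up 8.44 ± 0.661% of the peaks of A chromosomes and 11.2 ± 0.283% of those of C chromosomes, again without overlap (exact permutation p = 1.08e-05). The lowest share was on A09, at 7.24%, and the highest of the A chromosomes was on A07, at 9.64%. C03, the chromosome of BnaC3.LFY, had 11.1%. The median fold per chromosome was 5.93 ± 0.136 on A and 6.17 ± 0.0592 on C (exact permutation p = 0.000195, adjusted p = 0.000633). Among peaks without the averaging sign the difference in strong share was 0.747 percentage points and passed (exact permutation p = 4.33e-05). Strong peaks are rare among them, since 94.6% of the highest decile of fold carried the sign. The size of this difference is therefore not comparable with that over all peaks. The difference in median fold, 0.0393, did not pass among peaks without the sign (exact permutation p = 0.0511). The median peak width was 364 ± 9.96 bp on A and 366 ± 1.92 bp on C (exact permutation p = 0.522). The averaging sign was present in 65.4 ± 2.13% of A peaks and 67.0 ± 0.588% of C peaks (exact permutation p = 0.0402, adjusted p = 0.0872). Leaving out each of the 19 chromosomes in turn moved the difference in strong peaks between 1.94 and 2.14 per Mb and that in all peaks between 1.04 and 3.92 per Mb, the latter without A09 (exact permutation p = 0.0705).

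**Figure D2:**
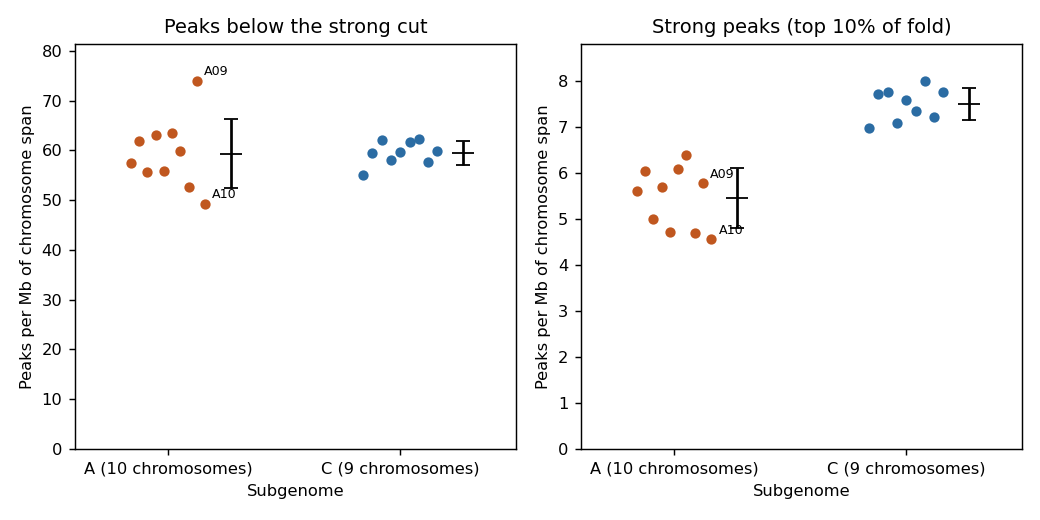
Peaks per Mb of chromosome span (vertical axes, from 0) for peaks below the fold of strong peaks (left) and strong peaks (right); each point is 1 chromosome, and the bars beside them are the mean ± SD of 10 A or 9 C chromosomes. The A and C points overlap on the left, while on the right all C points (6.99 to 8.01) lie above all A points (4.56 to 6.38).

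The C to A ratio of density climbed with the strength of the peaks. Below a fold of 4 the ratio was 0.970, and between 4 and 6 it was 0.969. Between 6 and 8 it was 0.991 and between 8 and 10 it was 1.04, and in none of these 4 classes did the subgenomes differ by more than the chromosomes' spread (exact permutation test, adjusted p between 0.585 and 0.867). The ratio was 1.13 between 10 and 15 (adjusted p = 0.0409, exact permutation) and 1.21 between 15 and 20 (adjusted p = 0.00759). Between 20 and 30, A chromosomes held 2.19 ± 0.274 and C chromosomes 3.11 ± 0.161 peaks per Mb, a ratio of 1.42 (exact permutation, adjusted p = 8.66e-05). From a fold of 30 upwards the values were 1.07 ± 0.269 and 1.74 ± 0.158, a ratio of 1.62 (exact permutation, adjusted p = 0.000217).

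**Figure D3:**
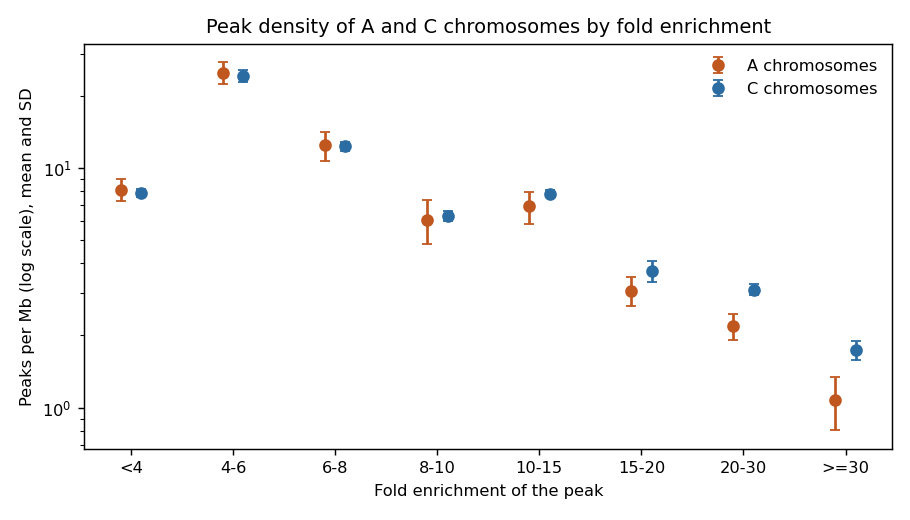
Peaks per Mb (log axis) in 8 classes of fold enrichment, as mean ± SD over 10 A chromosomes (orange) and 9 C chromosomes (blue). The means coincide in the classes below a fold of 10 and separate above it, to 1.07 against 1.74 per Mb from a fold of 30 upwards.

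Along the chromosomes the peaks were spread less evenly than random placement gives. The variance of peaks per 100 kb window divided by its mean was lowest on C05, at 1.38, which exceeds the highest value of any chromosome in 1000 random placements (1.35). A chromosomes were more uneven than C chromosomes, with ratios of 2.76 ± 0.806 and 1.75 ± 0.212 (exact permutation p = 0.000314, adjusted p = 0.000816). All chromosomes but C07 had at least 1 interval of 500 kb or more without a peak, 48 in all, where random placement gave 0. The longest was on C04, 2.82 Mb from 23942677 to 26763269. C01 had a peak-free interval of 2.36 Mb from 26471084 to 28829636, and C09 one of 1.88 Mb from 32403098 to 34282321. On the A chromosomes the longest were on A08, 1.86 Mb from 6519291 to 8378573, and on A03, 1.76 Mb from 37561793 to 39321516. On C03 the longest ran from 46764468 to 48069322. The mean of the longest interval per chromosome was 1.22 ± 0.401 Mb on A and 1.49 ± 0.762 Mb on C (exact permutation p = 0.331). Unresolved bases in the assembly cannot hold a peak and were not located here.

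**Figure D4:**
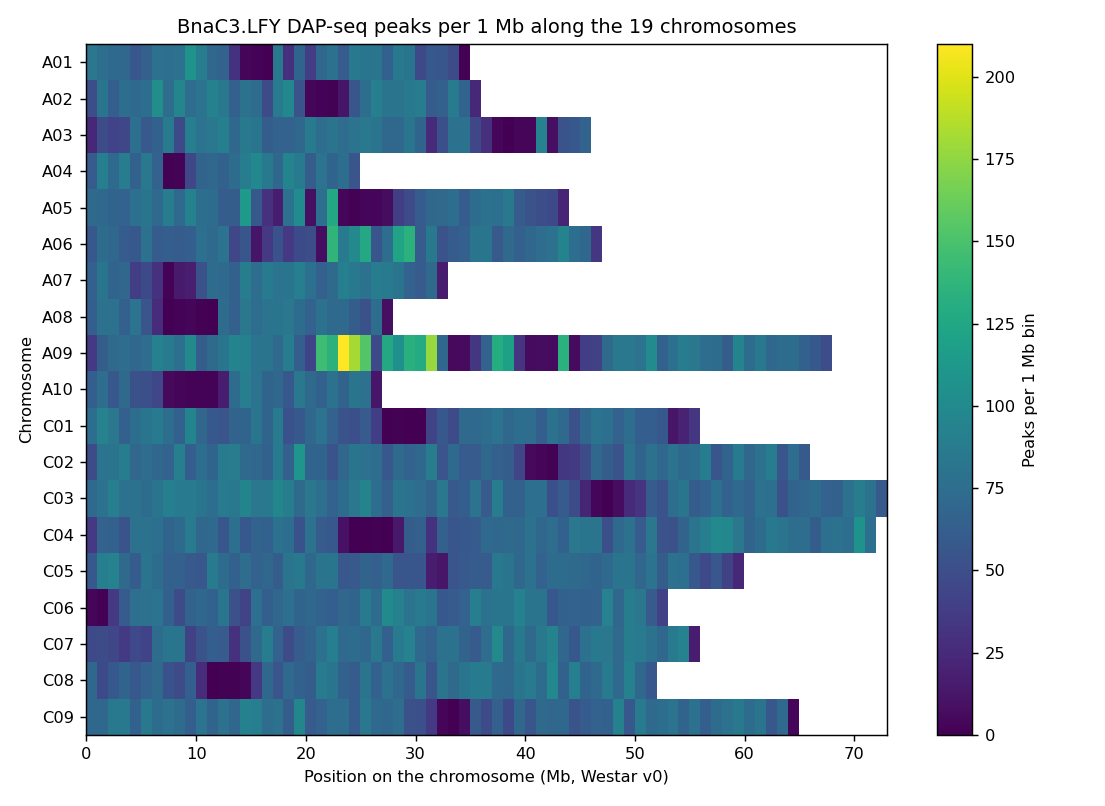
Peaks per 1 Mb bin (colour) along the 19 chromosomes (rows) against position in Mb on Westar v0; white lies beyond the last peak, and the last bin of each row is incomplete. Nearly every chromosome has a dark stretch with few or no peaks, and bright stretches stand out on A09, A06 and A05.

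Some stretches were crowded with peaks, almost all of them on A chromosomes. Of the windows with at least 20 peaks, against a mean of 6.68 per window, 59 were on A and 1 on C chromosomes, where random placement gave means of 0.231 and 0.148. The contrast depends on this minimum: at 15 peaks, which was tried first, 165 windows were on A and 89 on C chromosomes. The 59 windows of at least 20 peaks on A chromosomes lay on A09 (36 windows), A06 (10), A05 (9), A01 (3) and A03 (1). The number of such windows per chromosome did not pass the test between subgenomes (exact permutation p = 0.104). Of the 10 A chromosomes, 5 had none. The largest stretch, on A09 from 21.4 to 25.8 Mb, held 782 peaks, or 178 per Mb against 79.8 over the whole chromosome. A second on A09, from 30.8 to 31.9 Mb, held 187 per Mb. On A06 the stretch from 22.3 to 24.1 Mb held 135 per Mb. On the 5 A chromosomes, the dense windows held broader peaks than the other windows (median 476 against 366 bp) and carried the averaging sign more often (77.7 against 66.1%). Among peaks narrower than 472 bp the sign was present in 61.6% in dense windows (95% Wilson interval 57.9 to 65.1%) and in 59.1% in other windows (58.2 to 59.96%), so the difference seen over all widths was not detectable among them. The median fold was higher in them, 6.70 against 5.98 over the 5 chromosomes together, and lower only on A05 (6.02 against 6.08). Strong peaks nevertheless made up a smaller share of the peaks in dense windows, at 5.23% (95% Wilson interval 4.18 to 6.52%) against 8.30% (7.86 to 8.75%) over the 5 chromosomes together, where A09 gave 858 of the 1397 peaks in dense windows. A smaller share among more peaks does not mean fewer strong peaks per Mb. The A09 stretch from 21.4 to 25.8 Mb held 44 strong peaks in all. The 1 Mb bins of A09 that start at 21, 22, 23, 24 and 25 Mb held 22, 11, 8, 6 and 5, against 5.78 per Mb over A09. The A09 stretch from 28.8 to 29.2 Mb held 0 strong peaks. By chromosome, A01 had the higher share in dense windows (9.86 against 8.88%), and A03 had 7.41% (2.06 to 23.4%) against 8.25%. The recovered background, known for some peaks without the averaging sign, had a median of 1.59 reads in dense and 2.24 reads in other windows. The dense stretches of the A chromosomes lay at a median of 4.09 Mb from the nearest peak-free interval of 500 kb or more, against 11.2 Mb for random windows of the same chromosomes (one-sided permutation p = 0.00599, 17 stretches). Without A09 the distances were 5.81 and 10.4 Mb and the difference no longer passed (one-sided permutation p = 0.0849, 9 stretches). The random windows were drawn independently, whereas several stretches lie near each other on the same chromosome. Both p-values may therefore be too small, and this test was chosen after the data were seen.

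Over all chromosomes together, neighbouring peaks lay close together slightly more often than their regional density gives. Of 53686 neighbouring pairs in the same window, 6.08% had edges within 500 bp, against 4.74 ± 0.0880% (SD over 1000 random placements), a ratio of 1.28 (one-sided permutation p = 0.001, the smallest that 1000 placements allow). The ratio was 1.55 on A chromosomes and 1.07 on C chromosomes, and it was highest on A09 (2.09), A06 (1.93) and A05 (1.83). It was between 0.881 and 1.22 on the other A chromosomes, and below 1 on A02, A08, A10, C03 and C06. Over chromosomes the ratios were 1.32 ± 0.454 on A and 1.07 ± 0.0798 on C, which did not pass the test of a difference (exact permutation p = 0.150). Without A09, the excess over all chromosomes was 0.747 instead of 1.34 percentage points, and without windows of 15 or more peaks it was 0.638. At 200 bp between edges, close pairs were rarer than in random placements, by a difference of -0.835 points, and placements allowed to overlap, with the distance kept at 500 bp, turned the direction to -2.03 points. Strong peaks had a close neighbour in 8.43 ± 2.98% of cases per chromosome and other peaks in 9.55 ± 4.12%, a difference that did not pass (exact permutation p = 0.0920, lower for strong peaks on 12 of 19 chromosomes).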

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

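The tests for dilution by crowded windows, caller noise, collapsed repeats and lower background were chosen after the results they bear on had been seen in part, and those within peaks carrying the averaging sign, of coverage and of fixed spacing before.

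Outside the chromosome comparisons, 635 peaks lay on unplaced scaffolds, and they are listed here because no comparison used them. The 3 scaffolds with most peaks, numbers 286, 2904 and 1716, held 473 of them, at 69.6, 66.9 and 84.6 peaks per Mb. The last lies above every whole chromosome (53.9 to 79.8), but it rests on 104 peaks over 1.23 Mb. A single 1 Mb bin of A09 held 210 peaks, so stretches of this length vary more than whole chromosomes. Strong peaks made up 9.45% of the scaffold peaks, between the mean shares of A and C chromosomes. Dixon's test was run on the span and the 13 measures compared between subgenomes, which made 28 groups of 9 or 10 chromosomes, and chance passes it in about 1 of 20 groups. A09 stood apart from the other A chromosomes in span (67.8 Mb) and in dense windows (36), and C09 from the other C chromosomes in dense windows (1 against 0), which any single window would give where all others have 0.

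Strong peaks were denser on every C chromosome than on every A chromosome, while weaker peaks were not. Without windows of 15 or more peaks, all peaks were denser on C by 4.86 per Mb (exact permutation p = 0.0164), and strong peaks by 2.11. The mean density of weaker peaks was then also higher on C, though this left out 165 windows on A and 89 on C. Dilution by weaker peaks can lower the share of strong peaks but not their number per Mb, which was 5.46 on A and 7.50 on C chromosomes. It therefore bears on the share only. Dilution by crowded windows is not the whole cause of the lower share on A chromosomes. Without windows of 15 or more peaks the difference in strong share was 2.60 percentage points, against 2.75 with them. Dilution by peaks without the averaging sign is not the whole cause of the lower share either. Among peaks with the sign the difference was 3.43 points (12.3 ± 1.21% on A, 15.7 ± 0.387% on C). Leaving out peaks without the sign raised the share on both subgenomes, because most strong peaks carry it. The size of 3.43 points is therefore not comparable with the 2.75 of all peaks, and only the remaining difference bears on the question. Higher coverage of C chromosomes in DAP and input libraries alike would raise -log10 p at matched fold, and this differed by 0.285% (standard error 0.659%); coverage that differs in DAP libraries only was not tested. What stays open, as hypotheses, is a true difference between the subgenomes in strong LEAFY sites or in the methylation that genomic DNA keeps in this assay, copies of an element that spread in the C genome, or an uneven assembly, and none of these was tested.

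Dense windows crowded on 5 A chromosomes, mostly A09, A06 and A05. Caller noise of a single peak call would lower the share of peaks with the averaging sign, which was instead 11.6 percentage points higher in these windows, although joined neighbours of 1 call may add to this, and among peaks narrower than 472 bp the shares were 61.6 and 59.1%. Collapsed repeats would raise the background, whereas the recovered background under peaks was different by -0.645 reads (157 peaks against 3064, nearly all from 1 family of rows). Its 95% interval of -0.876 to -0.377 redrew single peaks pooled over the 5 chromosomes. Peaks of the same window share a local background, so this interval may be too narrow. A fixed repeat unit particular to a window would make spacings recur inside it. Spacings matched within 5 bp 0.803 times as often inside a dense window as between dense windows (95% interval from 0.559 to an upper bound of 1.082). A unit shared by several dense windows would raise both shares, so this ratio cannot count against it. Spacings were taken between peak starts, which can shift from copy to copy, and the test was not tried on planted repeats. How far the ratio counts against a unit particular to a window is therefore unknown. A lower background that raises fold stays open as a part or the whole of the cause. Fold was divided by 1.37, the most that the background interval allows, which may be too little if that interval is too narrow. Windows chosen on a random part of the peaks then held, among the rest, 1.85 times as many peaks above the median fold as other windows (95% interval 1.51 to 2.22). A lower bound over 2 was set to exclude a lower background (the ratio was 2.55 with choice and count on the same peaks). Dispersed repeats that carry LEAFY sites, and reads placed at random among near-identical copies, could also give such windows and were not tested without the sequence.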

How the results depend on the processing

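No paired analysis was possible because the list holds 1 value per peak for both replicates together and the input has no numbered partner. For the same reason no replicate could be left out. Only the limits of -log10 q, the fold above the median and merging were chosen before the data were examined, and all other alternatives after. The alternatives that need bases other than N, gene numbers, motifs or gene positions were not run. Of 86 alternatives over 10 results, 66 kept direction and side of the threshold, stayed within 1.5 times for a count, or stayed within the 95% Wilson interval for the share with the averaging sign, which is narrow. The higher density and share of strong peaks on C chromosomes, the higher density from a fold of 30 upwards and the greater unevenness of A chromosomes passed their exact permutation tests under every alternative run for them, though limits of -log10 q and fold leave the strong peaks themselves untouched. The C minus A difference in unevenness, -1.01, shrank to -0.489 at a -log10 q of at least 10 and to -0.549 above the median fold. It was -0.578 without windows of 15 or more peaks and -0.228 among peaks without the sign, and it grew to -1.76 in windows of 200 kb. Merging changed nothing since no intervals overlap. The list fell to 31873 peaks at a -log10 q of at least 10 and to 31475 above the median fold, and it split into 41915 peaks with and 21034 without the averaging sign. The sign was present in 74.6% of peaks at a -log10 q of at least 5, in 90.5% at 10, in 89.8% above the median fold and in 66.1% outside windows of 15 or more peaks. The difference of C minus A in all peaks per Mb, 2.25, became 3.37 at a -log10 q of at least 10, 3.27 above the median fold and 4.86 outside windows of 15 or more peaks, each then past 0.05, and it turned to -0.233 among peaks without the sign. The higher median fold of C chromosomes shrank to 0.0393 among peaks without the sign (exact permutation p = 0.0511). The excess of close neighbours turned to -0.835 percentage points at 200 bp between edges, to -2.03 points where placements could overlap, and to -2.25 points where they could overlap and midpoints within 1000 bp were counted. Counting such midpoints without overlap kept the excess, at 1.08 points, so the turn goes with the overlap. The 59 dense windows on A chromosomes became 165 at 15 peaks and 19 at 25 peaks, 19 among peaks with the sign, and 23 without A09. The cause of these changes was not tested, except where a stricter limit lowers counts by construction. Library depth is unknown, and its effect was not tested; peaks without the sign had a median pileup of 14 reads where it could be recovered.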

Other observations

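All values here were chosen after the data were seen. Windows without any peak were more frequent on A than on C chromosomes by count, 404 of 3838 against 311 of 5486 windows of 100 kb. At a minimum of 15 peaks, crowded windows were found on both subgenomes, 165 on A and 89 on C, and among peaks with the averaging sign these numbers were 74 and 2. The same minimum is stricter in that thinner list, and in all peaks a minimum of 20 gave 59 and 1. The fall on C chromosomes therefore does not show that their crowded windows lack the sign. The single window of 20 or more peaks on a C chromosome, on C09 from 19200001 to 19300000, held 24 peaks, of which 0 were strong and 62.5% carried the sign. The fullest windows were on A09, with 34 peaks from 25000001 to 25100000 and 33 from 31300001 to 31400000. The longest A chromosome after A09 had a span of 46.6 Mb.

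Of the rows without the averaging sign, the second curve relating p to q held 10531 and the first 5273. Which replicate each curve belongs to was not determined.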
